A study of Mus musculus with 4 samples.

How the data were processed

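The series holds 4 Affymetrix Mouse Gene 1.0 ST arrays of total RNA. There was 1 cerebellum of a wild-type mouse aged 2 months, 2 medulloblastomas of Math1-Cre;SmoM2 mice aged 1 and 2 months, and 1 medulloblastoma of a PtchLacZ/+ mouse aged 5 months. The groups, genotypes and ages were taken from the sample labels, which do not say from how many animals the samples came, so p-values may measure only the spread between these samples. Per the labels, the mice had a mixed genetic background and RNA was extracted from freshly removed tissue with a column kit.

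The log2 expression values were deposited by the authors as 1 table with 35557 probe sets and 4 columns. They were made with Affymetrix Expression Console, per the submitters' processing notes. Its version and the summarisation and normalization method are not given in the sources used here. The log2 scale was inferred from the range of the values, which ran from 2.71 to 14.9. The medians over all probe sets were 6.20 for the cerebellum, 6.12 and 6.36 for the SmoM2 tumours at 2 and 1 months, and 6.30 for the PtchLacZ/+ tumour. The values were used as deposited, with no further normalization and no filter. Over named genes, the array medians lay between 6.73 and 6.82. No detection calls were used, so a level under the lower quartile of named genes in its array (5.09 to 5.17) is not shown to be above background, and a difference from such a level is a lower limit. The number of arrays limits the precision.

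Probe sets were named through the platform annotation, and 21789 of them had a single gene symbol, 1621 had several and 12147 had none. Of the probe sets with a single symbol, 21695 matched a mouse RefSeq gene by Entrez identifier, from which the symbol and chromosome were updated (assembly GRCm38.p6). Coordinates of that assembly are not printed, since the build behind the array table is not given in the sources used here. For each of the 19938 genes with a single-symbol probe set, the probe set with the highest mean over the 4 arrays was used. This choice concerned 999 genes with more than 1 such probe set. Among the genes past the threshold in tumour against cerebellum, 218 had more than 1 probe set, and in 23 of these another probe set had a difference of the opposite sign.

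Tests of genes and lists used limma version 3.58.1 in R version 4.3.3 on the log2 values, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. The 3 tumours were compared with the cerebellum by lmFit and eBayes with 2 residual degrees of freedom. The PtchLacZ/+ tumour was compared with the 2 SmoM2 tumours in the same way with 1 residual degree of freedom. In both fits a lone sample was assumed to vary like the replicated group. Genotype and age cannot be told apart between the tumours. For the 1-month against the 2-month SmoM2 tumour no test was possible with 1 array each, and genes with a log2 difference of at least 1 were counted. A value after ± is limma's standard error unless SD is written.

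A total of 34 gene lists of pathways and cell types with 571 entries were fixed before the data were examined, of which 517 were measured, 1 of them through a synonym, for 511 different genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move, on balance, one way. Adjustment ran over the 34 lists. At the preset correlation camera takes its degrees of freedom from the number of genes and not of arrays. With an estimated correlation it uses the residual degrees of freedom, 2 and 1 in these fits. A list can then pass only with a very large statistic, and a miss does not show that it was unchanged. For the 1-month against the 2-month tumour, the median difference of each list was ranked among 10000 random lists of the same size, matched on mean expression in 20 classes. For each of 20 chromosomes and 6 pairs of arrays, the median difference of its genes above the median level was compared with that of 10000 random gene sets of the same size (a two-sided permutation of genes), adjusted over the 120 comparisons. Bootstrap intervals (95%) came from 2000 draws of genes, or of blocks of 20 neighbouring genes where stated.

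Named genes followed a rule set at the same time. It took Ptch1, Smo, Atoh1 and Gli1 in every sample. In tumour against cerebellum it took the 12 genes with the largest difference in each direction among those past the threshold with all 3 tumours on the same side. From each list it took the 2 members with the largest positive and the 2 with the largest negative difference in the comparison described, and any member of the Hedgehog and potassium channel lists. In PtchLacZ/+ against SmoM2 it took up to 10 genes per direction that lay at least 1 log2 unit beyond the nearer SmoM2 tumour, at a mean level above the median of named genes. In 1 month against 2 months it took 6 genes per direction at a mean level above that median.

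The fits were tested on simulated data made from the real array means. Among the 19938 genes, 67, 67 and 66 were given a log2 change of 1, 2 and 4. A further set of genes was given a log2 change of 2 to test camera. In tumour against cerebellum, 2.99%, 62.7% and 93.9% of genes with a simulated log2 change of 1, 2 and 4 were recovered. In PtchLacZ/+ against SmoM2 the shares were 0%, 1.49% and 89.4%. Far more genes, 3191, passed in the real tumour against cerebellum fit, where the adjusted threshold was thus less strict. The simulated shares for that comparison are therefore not those of the real data. In the real PtchLacZ/+ against SmoM2 fit 0 genes passed, so the adjusted threshold was stricter there than in the simulation. The simulated shares for that comparison are thus not the real power either.

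The alternatives tried were centring of each array on its median, quantile normalization, a filter that kept genes above the median level, the mean over the probe sets of a gene, a trended and robust prior variance (trended for the lists), leaving out each tumour in turn, 3 groups by genotype, limma's treat against a 2-fold difference, all probe sets of the table, and an estimated inter-gene correlation. A correction for gene length, which subtracted the median of each of 20 length classes from each array, was added after the data were seen. A different offset before taking log2 was not run, because the values already were log2. Probe sets with no symbol or several symbols were left out of the gene counts.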

Results

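Gene expression was measured in 3 mouse medulloblastomas and in 1 wild-type cerebellum, with 1 array for each. Medulloblastoma is a tumour of the cerebellum, and the form studied here arises from granule neuron progenitors with constitutive Hedgehog signalling. Of the tumours, 2 came from Math1-Cre;SmoM2 mice, in which an active form of the Hedgehog signal transducer Smoothened is switched on in the Math1 (Atoh1) lineage, at 1 and 2 months of age. The other came from a PtchLacZ/+ mouse at 5 months, which carries a lacZ allele of Ptch1, the receptor gene that holds Smoothened in check. They are called the SmoM2 tumours and the PtchLacZ/+ tumour. The cerebellum came from a mouse aged 2 months.

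The genes of the design were read in every sample first. The Ptch1 level was 10.24 on the log2 scale in the cerebellum, 11.88 and 11.55 in the SmoM2 tumours at 1 and 2 months, and 9.81 in the PtchLacZ/+ tumour. Ptch1 is itself a Hedgehog target. Which part of Ptch1 the lacZ allele replaces is not given in the sources used here, so the probe set may lie outside it and does not check the genotype. Smo was at 7.40 in the cerebellum, 10.02 and 10.69 in the SmoM2 tumours at 1 and 2 months, and 9.72 in the PtchLacZ/+ tumour. Whether the Smo probe set also reads the SmoM2 transcript was not determined, so its level in the SmoM2 tumours may not be that of the normal gene. Gli1, the transcription factor used as a readout of the pathway, was at 7.21 in the cerebellum, 9.37 and 9.29 in the SmoM2 tumours and 10.03 in the PtchLacZ/+ tumour. Atoh1, the transcription factor that marks granule neuron progenitors, was at 4.85 in the cerebellum, 11.39 and 11.84 in the SmoM2 tumours and 11.98 in the PtchLacZ/+ tumour. Smo and Atoh1 lie on chromosome 6, whose genes had a median shift against the cerebellum of -0.08 and 0.22 in the SmoM2 tumours at 1 and 2 months and of 0.32 in the PtchLacZ/+ tumour, relative to all other genes.

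The 3 tumours were first compared with the cerebellum, to ask which genes distinguish Hedgehog-driven medulloblastoma from normal cerebellum. Most mitosis and DNA replication genes rose and most markers of mature neurons fell. Atoh1 rose by 6.88 ± 0.28 on the log2 scale (adjusted p = 0.00295). Of the 12 rises named by rule, 3 were of the mitosis list (Ccna2, Top2a and Mki67), 3 of the granule neuron progenitor list (Atoh1, Nhlh1 and Ccnd2) and 1 of the Hedgehog list (Sfrp1). Ccna2 (cyclin A2) rose by 6.34 ± 0.19, the G1 kinase gene Cdk6 by 6.08 ± 0.43, Top2a (topoisomerase II alpha) by 5.78 ± 0.19, the cytokinesis gene Ect2 by 5.73 ± 0.17, Pclaf, whose product binds PCNA, by 5.64 ± 0.18, the proliferation marker Mki67 by 5.41 ± 0.41 and Ccnd2 (cyclin D2) by 5.35 ± 0.36. The neural transcription factor genes Nhlh1 and Olig3 rose by 5.75 ± 0.34 and 5.44 ± 0.38. Sfrp1, a gene of the Hedgehog list that encodes a secreted Wnt antagonist, rose by 5.72 ± 0.25, and Lcn2 (lipocalin 2) by 5.51 ± 0.34. Among these genes the highest adjusted p was 0.00427. Atoh1, Ccna2, Ect2, Nhlh1 and Olig3 were at 4.85, 4.61, 4.45, 4.44 and 4.22 in the cerebellum, under the lower quartile of that array (5.09) and not shown to be above background. Their differences are thus lower limits and are not ranked.

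Of the 12 falls named by rule, Ppp1r17 and Arhgef33 were of the Purkinje cell list and Vsnl1 and Calb2 of the mature granule neuron list. Ppp1r17, a phosphatase inhibitor gene of Purkinje cells, fell by 5.55 ± 0.85 (adjusted p = 0.0165), the neuronal calcium sensor gene Vsnl1 fell by 5.48 ± 0.95 (adjusted p = 0.0227) and Olfm3 fell by 4.93 ± 0.38 (adjusted p = 0.00442). Falls followed in Arhgef33 (-4.88 ± 0.83), the neuron-specific enolase gene Eno2 (-4.83 ± 0.62), the sodium channel subunit gene Scn2b (-4.60 ± 0.69), Car4 (-4.59 ± 0.56), the sialyltransferase gene St8sia5 (-4.43 ± 0.50), Spock3 (-4.43 ± 0.46), the calretinin gene Calb2 (-4.42 ± 0.38), Strip2 (-4.38 ± 0.35) and Chn2 (-4.38 ± 0.81). Ppp1r17 and Arhgef33 were at 3.73 and 4.85 in the PtchLacZ/+ tumour, and Spock3 was at 4.70, 4.43 and 3.59 in the 3 tumours, levels not shown to be above background, so these differences are lower limits. Gabra6, the receptor subunit gene of mature granule neurons, differed by -5.57 ± 1.31 but did not pass (adjusted p = 0.0509). It was at 12.24 in the cerebellum, 7.97 and 7.40 in the SmoM2 tumours and 4.64 in the PtchLacZ/+ tumour, and passed when any of the tumours was left out, with an adjusted p = 0.0188 without the 2-month SmoM2, 0.0315 without the 1-month SmoM2 and 0.0125 without the PtchLacZ/+ tumour.

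In all, 3191 of 19938 genes differed between tumours and cerebellum at an adjusted p under 0.05, of which 1336 were higher and 1855 lower in the tumours. A difference of at least 2-fold was present in 2683 of them, 1104 higher and 1579 lower. All 3 tumours lay on the same side of the cerebellum for all 3191 genes, which a test on these same tumours nearly requires. The spread came from the 3 tumours, and the single cerebellum was assumed to vary like them. The count was 6010 without the 2-month SmoM2 tumour, 2284 without the 1-month SmoM2 tumour and 1565 without the PtchLacZ/+ tumour. Without the PtchLacZ/+ tumour 21 named genes missed the threshold (adjusted p = 0.0552 to 0.126), among them Polr1b, Fbl, Ndufs1, Cox7a2, Stx1a, Scn3b, Ifit2, Ift140, Gusb, Col3a1, Slc6a13, Alas2, Tek, Kcnc2 and Kcnd3, and without the 1-month SmoM2 tumour 10 of these 21 did (adjusted p = 0.0548 to 0.0920).

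Mitosis and DNA replication genes rose nearly without exception. All 27 measured mitosis genes rose, with a median difference of 4.09, 4.24 and 4.29 in the SmoM2 tumours at 1 and 2 months and the PtchLacZ/+ tumour, and all 27 passed when adjusted over the list alone (camera adjusted p = 1.41e-27). Of 28 DNA replication genes, 25 rose, and 26 passed when adjusted over the list alone, with a median difference of 2.66 (camera adjusted p = 3.21e-18). Uhrf1, which couples DNA methylation to replication, rose by 5.03 ± 0.33, and the helicase subunit gene Mcm6 by 4.33 ± 0.22. Of 18 ribosome biogenesis genes, 7 rose and 14 passed when adjusted over the list alone, among them Polr1b (1.91 ± 0.35) and Fbl (1.85 ± 0.42), with a median difference of 0.89 (camera adjusted p = 1.39e-06). Of 14 CDK inhibitor and p53 target genes, 3 rose both over all genes and when adjusted over the list alone, and the list passed with a median difference of 0.45 (camera adjusted p = 0.00716). Those included Eda2r, a receptor gene induced by p53 (4.29 ± 0.18), and the CDK4 and CDK6 inhibitor gene Cdkn2c (2.95 ± 0.33). Each of these 4 lists had an adjusted p = 0.486 with an estimated correlation.

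Of 21 measured Hedgehog pathway and target genes, 13 rose and 16 passed when adjusted over the list alone, with a median difference of 1.43 (camera adjusted p = 2.40e-08, adjusted p = 0.486 with an estimated correlation). Sfrp1 rose by 5.72 ± 0.25, Mycn by 4.66 ± 0.22, the cell cycle transcription factor gene Foxm1 by 4.22 ± 0.29, Ccnd1 (cyclin D1) by 3.41 ± 0.38 and the chemokine receptor gene Cxcr4 by 3.24 ± 0.40. Smo rose by 2.74 ± 0.40, Gli2 by 2.49 ± 0.25, Gli1 by 2.36 ± 0.34 and Sufu, a negative regulator of the Gli factors, by 2.04 ± 0.18. The coreceptor genes Gas1 and Boc rose by 1.26 ± 0.24 and 1.15 ± 0.23, Evc2 by 1.15 ± 0.21 and Bmi1 by 1.06 ± 0.19. Ptch1 differed by 0.84 ± 0.83 (adjusted p = 0.600), Hhip, a Hedgehog-binding antagonist and target gene, by 1.77 ± 0.43 (adjusted p = 0.0554), Gli3 by -0.83 ± 0.30 (adjusted p = 0.147) and Igf2 by -0.19 ± 0.20 (adjusted p = 0.620). Hhip passed without the 2-month or the 1-month SmoM2 tumour (adjusted p = 0.00368 and 0.0382), and Gas1, Boc, Evc2 and Bmi1 did not pass without the PtchLacZ/+ tumour (adjusted p = 0.0658, 0.0905, 0.0919 and 0.0965).

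**Figure D1:**
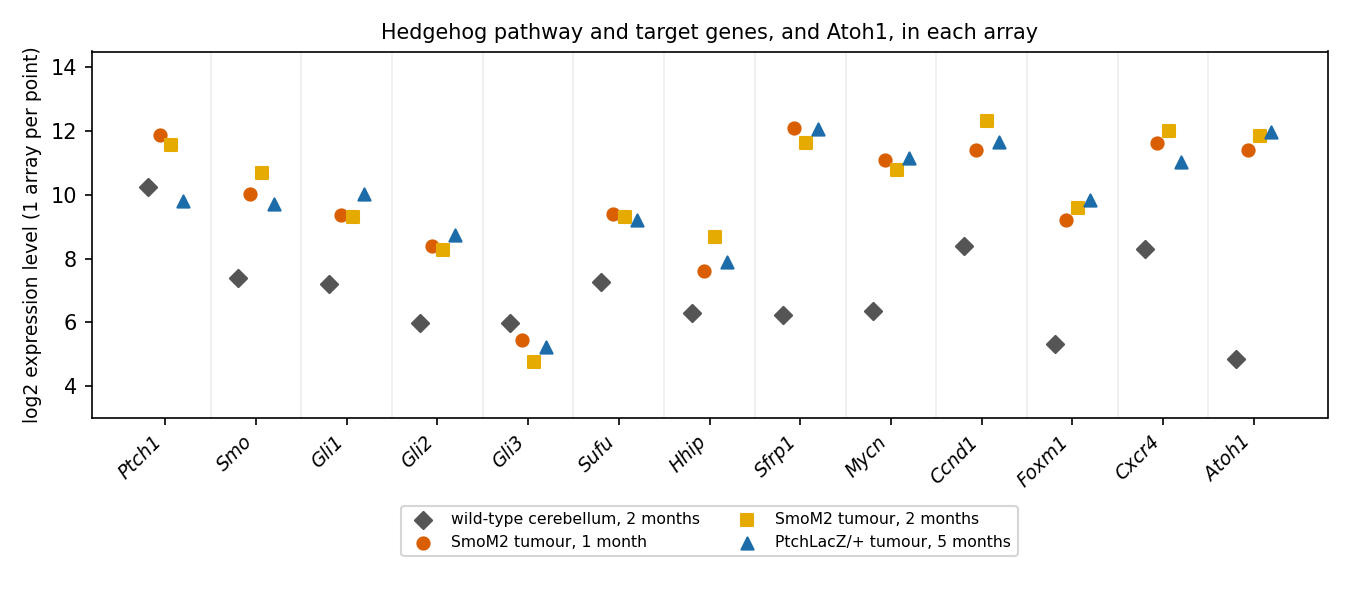
Log2 expression levels (vertical axis) of 12 Hedgehog pathway and target genes and of Atoh1 (horizontal axis), with 1 point for each of the 4 arrays and no error bars. Atoh1 was at 4.85 in the cerebellum and at 11.39 or above in the tumours, and Ptch1 was at 9.81 in the PtchLacZ/+ tumour, below the cerebellum at 10.24 and both SmoM2 tumours.

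Of the markers of immature cells of the granule lineage, a minority passed as higher. Of 16 granule neuron progenitor markers, 5 rose, and the same number passed when adjusted over the list alone, with a median difference of 1.22 (camera adjusted p = 5.68e-05). Atoh1 and Nhlh1 were among those that rose, while Eya1 differed by -0.50 ± 0.22 (adjusted p = 0.207) and Zic2 by -0.31 ± 0.32 (adjusted p = 0.624). Of 17 migrating and immature neuron markers, 8 rose, with a median difference of 1.74 (camera adjusted p = 0.000143). When adjusted over the list alone, 10 were higher and 1 was lower. Sox11 rose by 5.19 ± 0.37 and Igfbpl1 by 4.80 ± 0.37. Neurod1 differed by -1.23 ± 0.49 (adjusted p = 0.175) and Stmn2 by -1.30 ± 0.44 (adjusted p = 0.124). Of 11 neural stem cell markers, 2 rose, including the intermediate filament gene Nes (3.03 ± 0.33), with a median difference of 0.68 (camera adjusted p = 0.0295). When adjusted over the list alone, 6 of these were higher and 1 was lower. The adjusted p was 0.486 with an estimated correlation for each of the 3 lists. In fry it was 0.0728, 0.0752 and 0.110 in the order given.

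Most markers of mature neurons, astrocytes and oligodendrocytes fell. Of 16 mature granule neuron markers, 12 fell and all 16 passed when adjusted over the list alone, with a median difference of -3.31 (camera adjusted p = 3.47e-11). Of 13 Purkinje cell markers, 10 fell and 12 passed when adjusted over the list alone (median -3.80, camera adjusted p = 5.28e-07), although Foxp2 differed by 1.46 ± 0.68 (adjusted p = 0.240). Of 11 inhibitory interneuron markers, 8 fell and 8 passed when adjusted over the list alone (median -1.75, camera adjusted p = 3.26e-06), with Gad2, which encodes a GABA-synthesising enzyme, at -3.95 ± 0.43 and the vesicular GABA transporter gene Slc32a1 at -3.31 ± 0.34. Of 15 astrocyte and Bergmann glia markers, 9 fell and 11 passed when adjusted over the list alone (median -1.98, camera adjusted p = 1.39e-06). The connexin gene Gja1 fell by 3.05 ± 0.64 and Aldoc fell by 2.84 ± 0.58, while Gfap differed by 1.17 ± 0.46 (adjusted p = 0.173). Of 14 oligodendrocyte markers, 11 fell and 13 passed when adjusted over the list alone (medians -1.86 and -1.85 in the SmoM2 tumours and -2.57 in the PtchLacZ/+ tumour, camera adjusted p = 1.66e-07), among them the myelin genes Ermn (-3.35 ± 0.35) and Mag (-3.28 ± 0.68). Each of the 5 lists had an adjusted p = 0.486 with an estimated correlation.

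Oligodendrocyte precursor markers had a median in the other direction from those of mature oligodendrocytes. Of 9 measured, 5 rose and 8 passed when adjusted over the list alone, with a median difference of 1.49 (camera adjusted p = 2.16e-05, adjusted p = 0.486 with an estimated correlation). C1ql1 rose by 3.82 ± 0.21 and the growth factor receptor gene Pdgfra by 3.38 ± 0.27, and Nkx2-2 differed by -0.10 ± 0.21 (adjusted p = 0.823). Of 17 microglia and macrophage markers, 9 rose and 11 passed when adjusted over the list alone, with a median difference of 1.19 (camera adjusted p = 1.19e-06, adjusted p = 0.486 with an estimated correlation). Lysozyme (Lyz2) rose by 5.21 ± 0.48 and the lysosomal macrophage gene Cd68 by 3.17 ± 0.30, while the microglial gene Tmem119 differed by -0.09 ± 0.25 (adjusted p = 0.870).

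Genes of neuronal signalling were compared next. Of 17 synaptic vesicle and release genes, 13 fell and 1 rose, and 14 were lower and 1 higher when adjusted over the list alone (median -2.58, camera adjusted p = 2.03e-08). Unc13c fell by 4.03 ± 0.48 and the calcium sensor gene Syt1 fell by 3.95 ± 0.36, and Stx1a rose by 1.25 ± 0.24. Of 16 ionotropic glutamate and GABA receptor genes, 9 fell and 11 passed when adjusted over the list alone (median -1.93, camera adjusted p = 1.57e-06), including Gabrb2 (-4.04 ± 0.46). Of 21 voltage-gated sodium and calcium channel genes, 8 fell and 2 rose, with 9 lower and 2 higher when adjusted over the list alone (median -1.17, camera adjusted p = 0.00291). Scn1a fell by 4.31 ± 0.37, whereas Scn3a rose by 1.68 ± 0.19 and Scn3b by 1.65 ± 0.30. With an estimated correlation, the synaptic and receptor lists had an adjusted p = 0.486 and the sodium and calcium channel list an adjusted p = 0.499.

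The voltage-gated potassium channel list as a whole did not pass (median -0.06 over 28 genes, camera adjusted p = 0.0716), while 10 members fell, and adjusted over the list alone 10 were lower and 3 higher. The list passed as lower after quantile normalization (median -0.08, adjusted p = 0.0464), among genes above the median level (median -1.70, adjusted p = 0.0227) and without the 1-month SmoM2 tumour (adjusted p = 0.0309, although its median was then 0.0057). Those that fell were Kcnc1 (-3.35 ± 0.45), Kcna1 (-3.34 ± 0.30), Kcnd2 (-3.26 ± 0.19), Kcnh1 (-3.17 ± 0.22), Kcng4 (-2.93 ± 0.35), Kcna6 (-2.75 ± 0.47), Kcna2 (-2.45 ± 0.29), Kcnc4 (-2.16 ± 0.26), Kcnc2 (-1.09 ± 0.22) and Kcnd3 (-0.94 ± 0.18). Differences in the other direction were measured for Kcnh5 (2.72 ± 0.71, adjusted p = 0.0668), Kcnh7 (1.89 ± 0.57, adjusted p = 0.0937) and Kcnb2 (1.72 ± 0.80, adjusted p = 0.242), which passed without the 2-month SmoM2 tumour with an adjusted p = 0.00153, 0.00696 and 0.000760.

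Of 23 oxidative phosphorylation genes, 4 fell and 16 passed when adjusted over the list alone (median -0.75, camera adjusted p = 5.28e-07), among them Ndufs1 (-1.23 ± 0.18) and Cox7a2 (-1.23 ± 0.22). Of 15 glycolysis genes, 7 fell and 1 rose, with 9 lower and 2 higher when adjusted over the list alone (median -1.10, camera adjusted p = 0.00115). Eno2, the neuronal enolase gene, and Pfkp, which encodes a phosphofructokinase, fell (-4.83 ± 0.62 and -2.69 ± 0.26), and Hk2, the hexokinase common in proliferating cells, rose by 2.39 ± 0.23. Of 14 hypoxia response genes, 5 fell, with 6 lower and 1 higher when adjusted over the list alone (median -0.48, camera adjusted p = 0.0214), including Bnip3 (-1.93 ± 0.27) and Pdk1 (-1.78 ± 0.17). Of 13 Notch pathway genes, 2 rose, over all genes and when adjusted over the list alone (median 0.52, camera adjusted p = 0.0467), with the ligand gene Jag1 up by 1.99 ± 0.22, but the list missed the threshold without the 2-month SmoM2 tumour (adjusted p = 0.0509), with a trended prior variance (adjusted p = 0.0546) and with gene length classes centred (adjusted p = 0.0870). The hypoxia list missed it among genes above the median level (adjusted p = 0.242). With an estimated correlation the hypoxia list had an adjusted p = 0.499 and the other 3 an adjusted p = 0.486.

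Of the remaining lists none passed in tumour against cerebellum at the main settings. Among 11 lymphocyte markers (median 0.18, camera adjusted p = 0.237) and 8 choroid plexus and ependymal markers (median 0.30, camera adjusted p = 0.824) no gene passed. Without the 2-month SmoM2 tumour, the choroid plexus gene Ttr differed from the cerebellum by 4.82, Kl by 0.69 and Kcnj13 by -0.89. Of 13 endothelial cell markers (median -0.00, camera adjusted p = 0.652, but 0.0391 and a median of -0.36 without the 2-month SmoM2 tumour) only Tek passed, at -1.07 ± 0.18, and of 15 mural cell, fibroblast and meningeal markers (median -0.17, camera adjusted p = 0.376) Col3a1 rose by 1.33 ± 0.25 while Ptgds and Slc6a13 fell (-3.05 ± 0.43 and -1.65 ± 0.25). The heme synthesis gene Alas2 fell by 0.96 ± 0.21 among 5 red blood cell markers (median -0.11, camera adjusted p = 0.339), the neuronal activity gene Arc fell by 1.37 ± 0.23 among 14 immediate early genes (median -0.01, camera adjusted p = 0.613), and Ifit2 rose by 1.65 ± 0.29 among 11 interferon response genes (median 0.23, camera adjusted p = 0.339). Nkd1, a feedback inhibitor of Wnt signalling, rose by 2.90 ± 0.33 and was the only gene past the threshold of 11 Wnt target genes (median 0.49, camera adjusted p = 0.240, but 0.0428 with a median of 0.60 among genes above the median level). Of 20 primary cilium genes (median -0.26, camera adjusted p = 0.339), 2 rose and 3 fell, among them Ift140 (1.32 ± 0.30) and Bbs4 (-1.48 ± 0.20). The 6 X-inactivation and Y-linked genes had a median of -0.98 (camera adjusted p = 0.596, but 0.0146 without the 1-month SmoM2 tumour), and of 9 reference genes (median 0.27, camera adjusted p = 0.551) Gusb rose by 1.41 ± 0.32. Adjusted over the list alone, the counts past the threshold were 3 in the mural cell, fibroblast and meningeal list, 6 in the cilium list, 1 each in the endothelial, red blood cell, immediate early, interferon and Wnt lists, and 0 in the lymphocyte, choroid plexus, X and Y and reference lists.

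**Figure D2:**
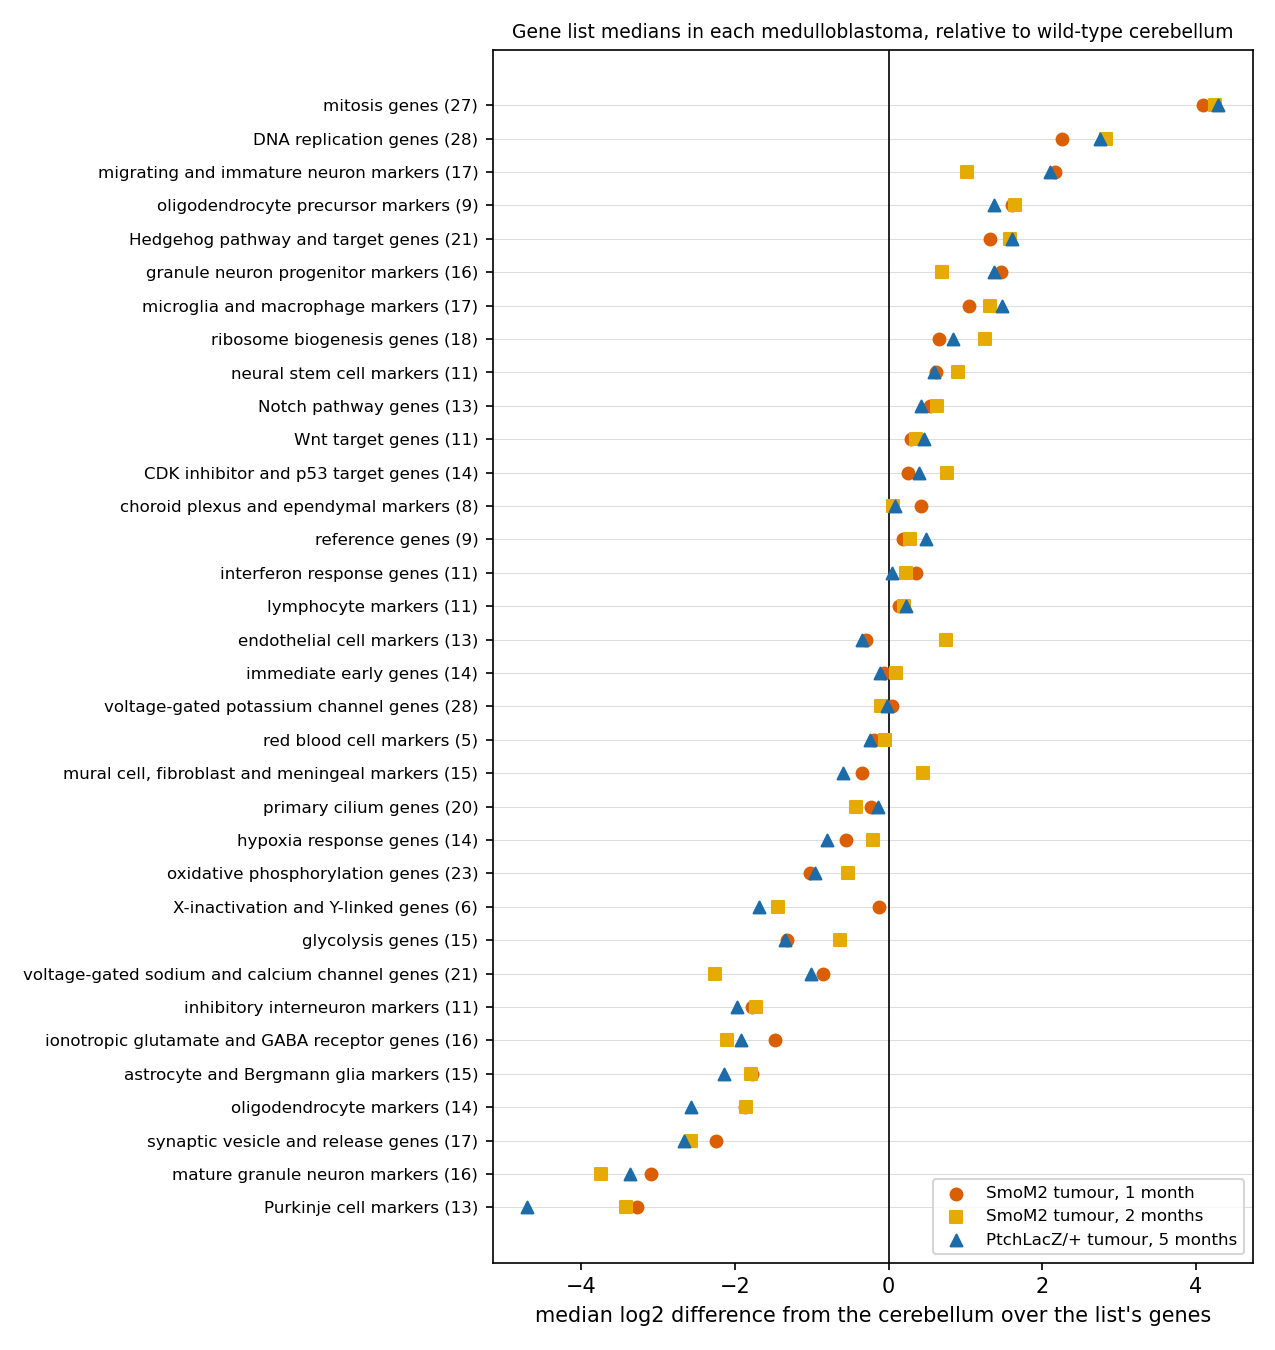
Median log2 difference from the cerebellum (horizontal axis) over the measured genes of each of the 34 lists (vertical axis, number of genes in parentheses), with 1 point for each tumour and no error bars. Mitosis genes lay highest, with medians of 4.09 and 4.24 in the SmoM2 tumours at 1 and 2 months and 4.29 in the PtchLacZ/+ tumour, and Purkinje cell markers were at -3.28, -3.42 and -4.70 in the same order.

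Across these lists camera called 22 of 34 at the preset correlation, 11 higher and 11 lower in the tumours, and 0 with an estimated correlation, where the lowest adjusted p was 0.486. The estimated form rests on 2 residual degrees of freedom, so only a very large statistic could have passed there. The rotation test fry called 4, the Hedgehog (adjusted p = 0.0170), mitosis (adjusted p = 0.0170), oligodendrocyte precursor (adjusted p = 0.0277) and mature granule neuron lists (adjusted p = 0.0297).

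The PtchLacZ/+ tumour was then compared with the SmoM2 tumours, to ask how tumours of the different Hedgehog pathway alleles differ, here the PtchLacZ/+ tumour at 5 months against the SmoM2 tumours at 1 and 2 months. Most Purkinje cell, astrocyte and oligodendrocyte markers were at lower levels in the PtchLacZ/+ tumour, as was Ptch1, although no gene passed the test at the main settings. The Purkinje cell gene Calb1 was at 4.45 in the PtchLacZ/+ tumour and at 8.05 and 7.96 in the SmoM2 tumours at 1 and 2 months. Car8, another Purkinje cell gene, was at 6.12 against 9.24 and 8.68, and the granule neuron genes Cbln3 and Gabra6 were at 5.83 against 8.81 and 8.40 and at 4.64 against 7.97 and 7.40. The levels of Calb1 and Gabra6 in the PtchLacZ/+ tumour were under the lower quartile of that array (5.14) and not shown to be above background, so their differences are lower limits. Ptch1 differed by -1.91 ± 0.28. Further from both SmoM2 tumours than 1 log2 unit on the low side were also Vsnl1 (-2.21 from their mean), Fam107a (-2.17), Hpca (-2.09), Pvalb (-1.85), Bmp5 (-2.93, with 7.02 and 9.70 in the SmoM2 tumours), Penk (-1.58) and Ndrg2 (-1.52).

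On the high side lay Rundc3b (1.47 above the SmoM2 mean), the transcription factor gene Foxp2 (1.47), Mroh2a (1.36), the microglial and macrophage genes Cst7 (1.32) and Itgam (1.20), the orphan receptor gene Gpr153 (1.31), the transferrin receptor gene Tfrc (1.30), Pde1c (1.25), the methyltransferase gene Prmt8 (1.22) and the Wnt antagonist gene Sfrp2 (1.14). Foxp2, Pde1c and Prmt8 are on chromosome 6, whose genes had a median 0.39 higher in the PtchLacZ/+ tumour than in the 1-month SmoM2 tumour and 0.08 higher than in the 2-month one, relative to all other genes. In total 17 genes were higher and 60 lower than both SmoM2 tumours by at least 2-fold.

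None of these genes passed in limma, where 0 genes had an adjusted p under 0.05 and the smallest was 0.990. At an unadjusted p under 0.05 there were 280 genes, against 996.9 by chance. With a trended and robust prior variance 3 genes were lower, Calb1 (adjusted p = 0.0174), Ppp1r17 (adjusted p = 0.0239) and Gabra6 (adjusted p = 0.0425), and among genes above the median level 4 were lower, Calb1 (adjusted p = 0.00102), Gabra6 (adjusted p = 0.00726), Car8 (adjusted p = 0.00916) and Cbln3 (adjusted p = 0.00916). Without a test, 187 genes lay at least 2-fold from the mean of the SmoM2 tumours, 64 higher and 123 lower, and the count was 178 without the 2-month SmoM2 tumour and 657 without the 1-month SmoM2 tumour.

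**Figure D3:**
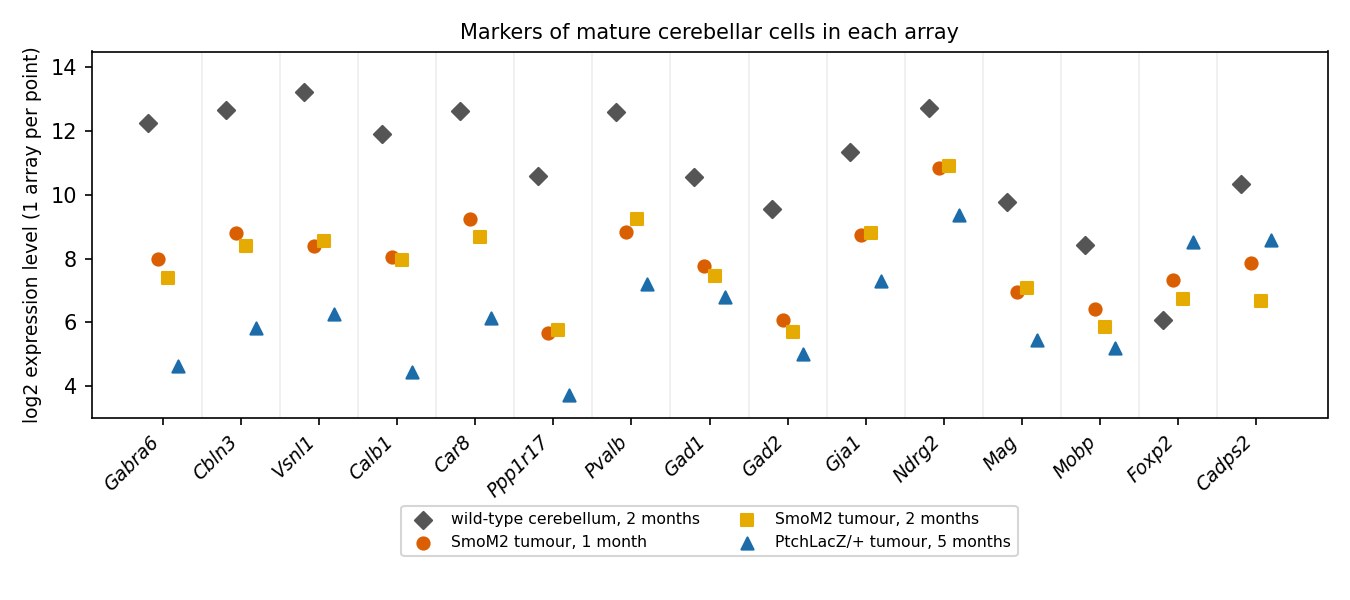
Log2 expression levels (vertical axis) of 15 markers of mature granule neurons, Purkinje cells, interneurons, astrocytes and oligodendrocytes (horizontal axis), with 1 point for each of the 4 arrays and no error bars. They were chosen from 69, of which 49 lay below both SmoM2 tumours in the PtchLacZ/+ tumour. Of those shown, Foxp2 and Cadps2 were above both and the other 13 were lowest in the PtchLacZ/+ tumour. Calb1 was at 4.45 in the PtchLacZ/+ tumour, 8.05 and 7.96 in the SmoM2 tumours and 11.92 in the cerebellum.

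By list, camera called 14 of 34 at the preset correlation, 10 lower and 4 higher in the PtchLacZ/+ tumour, 0 with an estimated correlation (lowest adjusted p = 0.831), and fry called 0. No member of any list passed over all genes. Adjusted over the list alone, the counts were 10 lower and 1 higher for Purkinje cell markers, 4 lower each for mature granule neuron and astrocyte markers, 1 lower each for the oligodendrocyte, Hedgehog (Ptch1) and receptor lists, 1 higher each for the potassium channel and reference lists, and 0 for the others. Purkinje cell markers had a median difference of -1.35, with 11 of 13 below both SmoM2 tumours (camera adjusted p = 1.06e-21, adjusted p = 0.831 with an estimated correlation). Astrocyte and Bergmann glia markers had a median of -0.66, with 12 of 15 below both (camera adjusted p = 1.58e-12, adjusted p = 0.831 with an estimated correlation), among them Gja1 (7.30 against 8.75 and 8.80). Oligodendrocyte markers had a median of -0.71, with 12 of 14 below both (camera adjusted p = 2.34e-12, adjusted p = 0.831 with an estimated correlation), among them Mag (5.45 against 6.94 and 7.07). By chance 33.3% of genes would lie below both.

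Mature granule neuron markers split. Gabra6 and Cbln3 were far lower in the PtchLacZ/+ tumour, while Cadps2 was at 8.59 against 7.87 and 6.67 and Il16 at 7.27 against 7.55 and 6.13, and the list had a median of -0.06 and a mean of -0.55 (camera adjusted p = 0.000636, adjusted p = 0.831 with an estimated correlation). The other lists called lower were glycolysis (median -0.37), mural cell, fibroblast and meningeal markers (-0.37), endothelial cell markers (-0.52), oxidative phosphorylation (-0.21), synaptic vesicle and release genes (-0.19) and hypoxia response genes (-0.19). Those called higher were granule neuron progenitor markers (0.26), DNA replication (0.15), primary cilium (0.13) and microglia and macrophage genes (0.12, but -0.13 among genes above the median level, where the list was not called). Their camera adjusted p ran from 0.000265 for glycolysis to 0.0356 for hypoxia, and each had an adjusted p = 0.831 with an estimated correlation. Among genes above the median level the endothelial, hypoxia, synaptic vesicle and cilium lists were not called (adjusted p = 0.232, 0.261, 0.0906 and 0.177), nor was the cilium list with a trended prior variance (adjusted p = 0.0613). The direction of 3 of these lists depended on the SmoM2 tumour taken, with medians against the 1-month and the 2-month tumour of 0.06 and -0.99 for endothelial markers, 0.46 and -0.16 for DNA replication (6 of 28 genes above both) and -0.01 and 0.59 for granule neuron progenitor markers. The Hedgehog list had a median of 0.21 and a mean of -0.04 and was not called (camera adjusted p = 0.490), with Gli1 at 10.03 against 9.37 and 9.29. Among potassium channel genes (median -0.09, mean 0.04, camera adjusted p = 0.953), Kcnh8 was at 7.21 in the PtchLacZ/+ tumour against 5.36 and 4.82, and Kcnh5 at 8.84 against 8.16 and 6.96. The median, mean and test also differed in sign for the sodium and calcium channel (median -0.05, mean 0.00099, test lower), Wnt target (0.01, -0.27, lower) and reference lists (-0.07, 0.09, higher), none of them called.

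The 1-month was set against the 2-month SmoM2 tumour, to ask how tumours of this genotype differ with age, with 1 array each and hence no test. By list median, neuronal channel and receptor genes and migrating neuron markers were at higher levels at 1 month, and endothelial and mural cell markers at 2 months. Ttr (transthyretin) was at 11.27 at 1 month and 4.50 at 2 months, a level not shown to be above background, and was at 10.81 in the PtchLacZ/+ tumour and 6.23 in the cerebellum. Higher at 1 month were also 2310067E19Rik (9.69 against 5.06, likewise not shown above background), the vesicular glutamate transporter gene Slc17a6 (by 3.50), Insyn2a (by 3.30), the nuclear long noncoding RNA Malat1 (by 3.17) and Gm7265 (by 2.98). Higher at 2 months were the macrophage metalloelastase gene Mmp12 (9.37 against 5.70), Angpt2, a vessel-remodelling ligand gene (8.99 against 5.66), the Wnt inhibitor gene Wif1 (9.43 against 6.58), the endothelial receptor gene Adgrl4 (9.31 against 6.58), Bmp5 (9.70 against 7.02) and Fgf5 (9.13 against 6.60).

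In total 740 genes lay at least 2-fold apart, 409 higher at 1 month and 331 higher at 2 months. The split was 477 and 256 with each array centred on its median and 510 and 245 after quantile normalization of these 2 arrays. Between the 1-month SmoM2 and the PtchLacZ/+ tumour 178 genes lay at least 2-fold apart, and between the 2-month SmoM2 and the PtchLacZ/+ tumour 657. The difference between the SmoM2 tumours, taken as 2 months minus 1 month, went down with gene length (Spearman rho = -0.40 across 9955 genes, which are not independent replicates), and the split was 308 and 351 with gene length classes centred, a correction chosen after seeing the data. The female-specific RNA Xist was at 9.50 in the 2-month and 4.16 in the 1-month tumour, and the Y-linked gene Eif2s3y at 3.63 and 8.17. These levels differ as between a female and a male animal, so age and sex cannot be told apart in this comparison.

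Endothelial cell markers had a median 1 month minus 2 month difference of -1.09 and mural cell, fibroblast and meningeal markers of -0.75, both below all of 10000 random lists (percentile 0). At least 2-fold higher at 2 months were 7 of the 13 endothelial genes, such as Emcn (7.29 against 5.68) and Pecam1 (7.63 against 6.30), and 6 of the 15 mural genes, such as Acta2 (8.48 against 6.58) and Vtn (10.11 against 8.25). DNA replication genes had a median of -0.56 (percentile 0), with Mcm2 at 11.19 at 2 months and 10.05 at 1 month. Oxidative phosphorylation (-0.45, percentile 0.05), immediate early genes (-0.48, percentile 0.11), ribosome biogenesis (-0.46, percentile 0.36) and glycolysis (-0.46, percentile 0.57) lay on the same side. So did CDK inhibitor and p53 target genes (-0.46, percentile 0.83), hypoxia response genes (-0.39, percentile 0.96) and reference genes (-0.47, percentile 1.69). Cdkn2a, the tumour suppressor gene of p16 and p19ARF, was at 8.44 at 2 months against 6.44 at 1 month.

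On the other side, migrating and immature neuron markers had a median of 0.94, with 7 of 17 at least 2-fold higher at 1 month, among them Nfia (12.50 against 10.98) and Cntn2 (10.87 against 9.43). Voltage-gated sodium and calcium channel genes had a median of 0.86, with 10 of 21 at least 2-fold higher at 1 month, among them Cacna1a (9.11 against 7.23). Ionotropic receptor genes (0.77), granule neuron progenitor markers (0.59, with Meis1 at 11.16 against 10.08) and synaptic vesicle genes (0.52) followed. Each of these 5 lists lay at the percentile 100 of its random lists, as did the X-inactivation and Y-linked genes (1.51), whose levels differ between the sexes. Mature granule neuron markers (0.37, percentile 99.9), potassium channel genes (0.21, percentile 99.9) and choroid plexus and ependymal markers (0.31, percentile 99.3) lay on this side too. Of the 34 lists, 30 kept the sign of their median under centring, quantile normalization and the gene length correction. The Hedgehog list, with a median of -0.05 (percentile 73.4), did not keep it, being at 0.02 with arrays centred and at 0.09 after quantile normalization. With gene length classes centred, medians were 0.72 for migrating neuron, 0.78 for sodium and calcium channel, 0.52 for receptor and 0.43 for synaptic vesicle lists. They were 0.16 for mature granule neuron and 0.12 for potassium channel lists, but 0.72 for progenitor and 0.37 for choroid plexus lists. The random lists were drawn gene by gene and not matched on gene length, so a percentile is a description and not a test.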

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

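No test in this part was chosen after its result was seen. Of 331 named genes and 34 lists, 3 genes lay on opposite sides of the cerebellum in the PtchLacZ/+ tumour and in both SmoM2 tumours, by at least 0.25 on the log2 scale. Ptch1 was at -0.43 against the cerebellum in the PtchLacZ/+ tumour and at 1.64 and 1.32 in the SmoM2 tumours at 1 and 2 months. Tfrc, the transferrin receptor gene, was at 0.75 in the PtchLacZ/+ tumour and at -0.55 and -0.54 in the SmoM2 tumours. Clic6, a chloride channel gene among the choroid plexus markers, was at -0.32 in the PtchLacZ/+ tumour and at 0.46 and 1.07 in the SmoM2 tumours. What drew attention was the opposite direction alone. Since the cerebellum is shared, the difference of these effects equals PtchLacZ/+ minus SmoM2, which had an adjusted p of 1.00 in limma for each.

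Of the 13768 probe sets without a single gene symbol, which were not used in the gene counts, 387 were at least 2-fold above the cerebellum in all 3 tumours and 386 at least 2-fold below it.

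Taking each array in turn as the lone sample against the other 3 gave 3191 genes for the cerebellum and 0 as the highest for any tumour, so 1 of 4 splits gave as many, and 4 splits are too few for a share under 0.05.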

How the results depend on the processing

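The gene length correction was chosen after seeing the data. Of 92 named genes past the threshold, 50 stayed past it under every alternative run for them. The count of 3191 genes in tumour against cerebellum was 1951 with 3 groups by genotype, 597 with treat against a 2-fold difference, 1616 with all probe sets of the table, and 1565 to 6010 when a tumour was left out. Treat asks for a larger difference, and for the other changes the cause was not tested. Lists called there numbered 22 to 24 when a tumour was left out. PtchLacZ/+ against SmoM2 gave 0 genes, 4 among genes above the median level and 3 with a trended and robust prior variance. The filter to genes above the median level also changed the prior variance, which was fitted anew to the genes kept. Why genes passed in these settings was not tested. The count of genes at least 2-fold apart there, without a test, was 178 to 657 when a SmoM2 tumour was left out. With an estimated correlation 0 lists were called in tumour against cerebellum and 0 in PtchLacZ/+ against SmoM2, where the few residual degrees of freedom left little power. Microglia and macrophage markers in PtchLacZ/+ against SmoM2 turned to a median of -0.13 among genes above the median level, where fewer members were left. Among the named genes, treat ended 42 calls, leaving out the PtchLacZ/+ tumour 21, the 3 groups 17 and leaving out the 1-month SmoM2 tumour 10, while leaving out the 2-month SmoM2 tumour added 28. No named gene reversed. Lists called in PtchLacZ/+ against SmoM2 only under an alternative were the ionotropic receptor (adjusted p = 0.0228 to 0.0456), migrating and immature neuron (0.0423 to 0.0487), neural stem cell (0.0252 and 0.0479) and choroid plexus lists (0.0188). The choroid plexus list was called only among genes above the median level, with a median of 2.92 against 0.07 over all 8 members. Ttr, a member above that level, had this same difference from the SmoM2 mean, so the call rests on Ttr. Its level differed by 6.78 between the SmoM2 tumours. Signal over background was not known, which limits what can be said of low levels.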

Other observations

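The tests of granule neuron differentiation and of the share of chromosome 17 genes were chosen after their results were seen. Among genes that differ between the sexes, Xist was at 4.91 in the cerebellum, 4.16 and 9.50 in the SmoM2 tumours at 1 and 2 months and 4.61 in the PtchLacZ/+ tumour. The Y-linked genes Eif2s3y and Uty were at 8.46 and 8.68 in the cerebellum and 8.17 and 8.51 in the 1-month SmoM2 tumour. They were at 3.63 and 4.04 in the 2-month SmoM2 tumour and at 3.48 and 3.76 in the PtchLacZ/+ tumour, which thus had low levels of Xist and of both Y-linked genes. Of the choroid plexus markers, Ttr was at 11.27 in the 1-month SmoM2 and 10.81 in the PtchLacZ/+ tumour, where Kl was at 5.52 and 5.26 and Folr1 at 6.19 and 6.49. Of 351 genes of small nucleolar and microRNA precursors, 48 were at least 2-fold higher in the 1-month than in the 2-month SmoM2 tumour and 0 were at least 2-fold higher in the 2-month tumour.

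The 2-month SmoM2 tumour stood apart from the other tumours, with 740 genes at least 2-fold from the 1-month SmoM2 tumour, against 178 between that and the PtchLacZ/+ tumour. After quantile normalization of all 4 arrays these counts were 773 and 186, a ratio of 4.16, and the ratio was 3.70 with gene length classes centred, which argues against array scaling or a trend with gene length as the whole cause. A lower share of nuclear RNA in that sample cannot be told apart. Malat1, Meg3 and Airn, chosen after their values were seen, differed by -3.17, -2.81 and -2.19 (2 months minus 1 month). The other nuclear RNAs measured, Rian and Snhg11, which decide the test, differed by -0.87 and 0.16. Their median of -0.36 lay between the bounds set for it. Rian was at 4.30 in the 2-month tumour, not shown to be above background, so its difference is a lower limit. In the PtchLacZ/+ tumour Malat1 and Airn were at 12.21 and 7.26, against 9.41 and 5.99 in the 2-month tumour. Meg3 and Rian were at 6.24 and 4.52 in the PtchLacZ/+ tumour, against 5.84 and 4.30. The low levels of Meg3 and Rian were thus not particular to the 2-month tumour. Age, sex and the tissue taken stay open, as untested.

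Most markers of mature cerebellar cells were lower in the PtchLacZ/+ than in the SmoM2 tumours, with 49 of 69 below both, and 98.0% of the 49 stayed so after quantile normalization, which argues against array scaling. Purkinje, oligodendrocyte and interneuron markers had a median of -0.71 over 38 genes (95% bootstrap interval -0.89 to -0.37), which argues against granule neuron differentiation in the SmoM2 tumours as the whole cause. By list the medians were -1.35, -0.71 and -0.30, so this rests mostly on the Purkinje and oligodendrocyte markers. The interval draws genes, which may move together, and does not measure the spread between tumours. Normal cerebellum mixed into the SmoM2 samples is a candidate explanation that cannot be told apart. The share it would need was 12.2% by astrocyte and 11.5% by oligodendrocyte markers but 6.22% by Purkinje and 4.24% by interneuron markers. By granule neuron markers it was 0.739% (95% bootstrap interval -3.17% to 2.96%). The ratio of highest to lowest, 16.6, passed the bound set beforehand for counting against mixing. The bootstrap limits, which were not part of that rule, were weighed too. The lower limit of the astrocyte share, 7.66%, over the upper limit of the granule neuron share was 2.59, under that bound. The granule neuron share was 3.06% from the 1-month and 0.241% from the 2-month SmoM2 tumour alone, where the highest list gave 11.4% and 12.2%, so the ratio rests on which tumour is taken. Genotype and age stay open, as untested.

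Relative to all other genes, the 494 genes of chromosome 6 had a median 0.33 higher in the 2-month SmoM2 and 0.39 higher in the PtchLacZ/+ than in the 1-month SmoM2 tumour, and the 457 genes of chromosome 17 a median 0.34 higher in the 2-month than in the 1-month SmoM2 tumour, none of 10000 random gene sets being as far from 0 (permutation of genes, p = 1e-04, the smallest they can give, adjusted p = 0.00171 over 120 comparisons, of which 17 passed, 9 of them on other chromosomes with medians from -0.17 to 0.09). The mean of the chromosome 6 shifts was 0.36 with gene length classes centred, and the lowest of 5 parts of the chromosome had 0.34, which argues against gene length or a few genes as the whole cause. After quantile normalization it was 0.35. A shift of a whole array cancels in a median relative to all other genes, so this value hardly tests array scaling. For chromosome 17 the median was 0.34 with gene length classes centred, which argues against gene length, and although the lowest of 5 parts had 0.20 (95% bootstrap interval 0.0828 to 0.370), 73.1% of its genes (68.5 to 77.5, over blocks of 20 neighbouring genes) lay above the median of all others, more than the 60% that 1 part of 5 could give, which argues against a few genes or a part of that size as the whole cause. A gain of a chromosome copy may be the source, in all or part of the cells. An added copy in every cell would raise the DNA dose by 0.58 on the log2 scale. How far array levels follow dose was not measured, so the share of cells cannot be told. A gain was not tested, as no DNA data were analysed here.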
